A study of Homo sapiens with 6 samples.

How the data were processed

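The data are 6 RNA-seq libraries of HCT116 cells, with the groups taken from the sample labels: parental or 5-fluorouracil resistant cells, each untransfected, with control siRNA or with EHMT2 siRNA. Each group holds 1 library here. The series description speaks of independent replicates, but none beyond the first of each group is among the files, so others were not analysed. The titles name the resistant cells alike, but another label of the untransfected resistant library names them in a different form than in the transfected resistant libraries. The series description gives both forms for resistant cells, and the libraries were grouped on that basis.

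Libraries were made from total RNA with the TruSeq RNA v2 kit, per the labels' protocols. The submitters' processing notes name FastQC 0.12.1, cutadapt 4.9, HISAT2 2.2.1, StringTie 2.1.1 and build GRCh38, without giving their order. The annotation release, the choice of genes and the strand setting are not given in the sources used here. The deposited values are FPKM, 1 table per library, as named by the files. The low values have no steps of whole reads, and the lowest value above 0 lay between 0.172 and 0.264 in each library. The number of reads is not given in the sources used here, so depth and counting error are unknown and no interval for counting error is given.

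Each table held 19957 rows. Where a symbol had more than 1 row, the row of highest mean FPKM was kept, which left 19942 symbols. Of these, 19887 had an entry in GENCODE 29 (build GRCh38), from which coordinates and exonic bases shared with other genes were taken. The rows of the untransfected tables stand in another order than those of the siRNA tables, and all tables were joined by gene.

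Differences between a pair of libraries were computed as log2 ratios after adding 1 to each FPKM. Genes with an FPKM of 1 or more in at least 1 library of the pair were counted when they were at least 2-fold apart. For 41 gene lists written before the data were examined, the median ratio of the members at 1 FPKM or more in any library was compared with 10000 random lists of the same size, matched on mean expression in 20 bins. A list was called apart outside the 2.5 to 97.5 percentile range, and lists with fewer than 5 measured members were left out of this comparison. On simulated data, 4 of 40 lists without a shift and 36 of 40 lists shifted by 0.5 fell outside that range. The simulated genes varied independently, so this gives no rate for real lists whose members vary together.

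An additive model with line and treatment was fitted to the log2 values with limma 3.58.1 in R 4.3.3, with a mean-variance trend, for 11521 genes at 1 FPKM or more in at least 3 libraries. The interaction of line and treatment serves as the error term. Benjamini-Hochberg adjustment with a threshold of 0.05 was made over all genes and over each list alone. The adjustment over a list alone does not correct for the number of lists, from which the members that passed were picked. The 6-library fit has 2 residual degrees of freedom before moderation. A fit restricted to the 4 siRNA libraries, which has 1, was among the alternatives fixed before the data were examined, and the report names this fit where its results are given. Tested on simulated data with the spread of the real 6-library fit, the model recovered 40% of log2 changes of 1 and 98% of log2 changes of 2 for EHMT2 siRNA, 58% and 98% for line, and called 0 genes when none was changed. Noise was drawn independently for each gene, so this gives no rate of false calls for real genes that vary together. The 4-library fit was not simulated.

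Genes are named by a rule fixed before the data were examined, among genes with an FPKM of 5 or more in at least 1 library of each pair. It took the 12 highest and 12 lowest by the smaller ratio of the untransfected and control siRNA line pairs, the 10 highest and 10 lowest by the smaller ratio of both knockdown pairs, and the 6 highest and 6 lowest by the difference between the knockdown ratios of the lines. EHMT2, EHMT1, TYMS, TYMP, DPYD, UMPS, TK1, UPP1 and CDKN1A were always named, with the 2 highest and 2 lowest members of lists described and members that passed a test. Some genes that the rule takes are withheld and are not named, while counts and medians of lists include them. Genes of the short arm of chromosome 18, the scan of 25-gene windows against 1000 shuffles of gene order and the gene HNF4A were chosen after their values were seen. The short arm was taken as the genes before the widest stretch of chromosome 18 without an expressed gene, with an interval from bootstrap resampling of genes.

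Alternatives were a pseudocount of 0.1, no filter or an FPKM of 5, median-centred ratios, values rescaled to the same sum in each library, thresholds of 1.5-fold and 4-fold, quantile normalisation, no trend, and leaving out each library in turn. Counts without genes that share 25% or more of their exonic bases with another gene, and the alternatives for the short arm of chromosome 18, were added after the data were seen. Calculations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.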

Results

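Messenger RNA was measured by RNA sequencing in 6 libraries of HCT116, an established human colorectal carcinoma cell line. The cells were either parental or had acquired resistance to 5-fluorouracil, a pyrimidine analogue whose metabolites block thymidylate synthase and enter RNA and DNA. Each kind of cell was left untransfected, given a control siRNA, or given an siRNA against EHMT2, which encodes the histone H3K9 methyltransferase G9a. These 6 groups held 1 library each, so no difference between a pair of libraries has a replicate check, and no p-value is given for a pair. The series asks what EHMT2 does in cells with acquired drug resistance. The deposited values are FPKM for 19942 gene symbols, of which 11245 to 11730 per library had an FPKM of 1 or more. The FPKM of a library summed to between 360730 and 446165. The files hold no read counts, so the sequencing depth is unknown. Ratios are log2 ratios of FPKM with 1 added, and gene coordinates are those of GENCODE 29 on build GRCh38.

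EHMT2 itself (ENSG00000204371, chromosome 6, 31879759 to 31897687) was lower in both libraries labelled as knockdown. In resistant cells its FPKM was 3.80 with EHMT2 siRNA and 19.5 with control siRNA, which is 19.5% of the control level and a log2 ratio of −2.09. In parental cells the values were 8.58 and 31.7, which is 27.1% of the control level and a log2 ratio of −1.77. Between the lines EHMT2 had no single direction. It was 27.3 in resistant and 19.8 in parental untransfected cells, a ratio of 0.44, but the ratio was −0.68 with control siRNA, and it was below 0 with EHMT2 siRNA too. In an additive limma fit over the 4 siRNA libraries, with line and treatment as terms, EHMT2 fell with its siRNA by 1.93 on the log2 scale (SE 0.14, adjusted p = 0.000774 with Benjamini-Hochberg adjustment). The limma fit over all 6 libraries gave the same estimate with an SE of 0.36 and an adjusted p of 0.0636 over all genes with Benjamini-Hochberg adjustment, and 0.0485 when adjusted over the list alone of H3K9 methyltransferases and readers. In the 4-library fit EHMT2 had a line coefficient of −0.84, lower in resistant cells (SE 0.14, adjusted p = 0.0225, limma with Benjamini-Hochberg adjustment), whereas the 6-library fit gave −0.41 (SE 0.30, adjusted p = 0.949) and no call. EHMT1, the partner of EHMT2 in the G9a-GLP complex, had ratios of only −0.08 in resistant and −0.15 in parental cells. SUV39H1, another H3K9 methyltransferase, had ratios of −1.02 and −0.91.

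**Figure D1:**
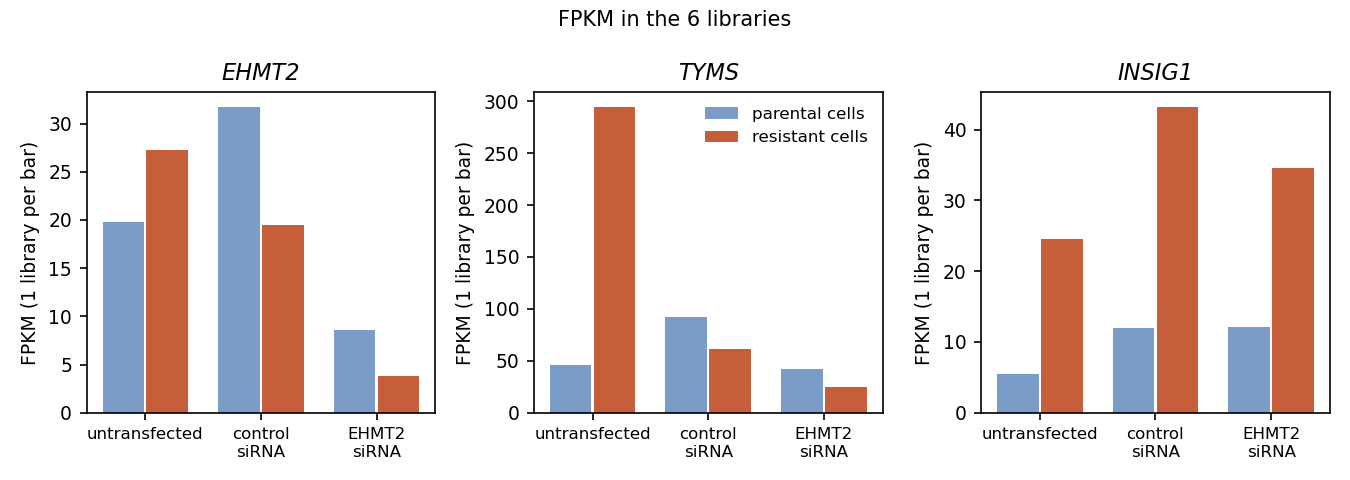
FPKM (vertical axis) of EHMT2, TYMS and INSIG1 in the 6 libraries, 1 bar per library, with parental cells in blue and resistant cells in orange. EHMT2 was lowest with its siRNA, TYMS stood at 294 in untransfected resistant cells alone, and INSIG1 was higher in resistant cells under all 3 treatments.

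The first comparison asked how 5-fluorouracil resistant cells differ from parental cells, and it was read in 3 pairs of libraries. Genes of cholesterol synthesis were higher in resistant cells under every treatment. The median ratio of the 26 measured members was 1.00 in untransfected cells, 0.73 with control siRNA and 0.57 with EHMT2 siRNA, above all random lists matched on expression (percentile 100 in each pair). Of these 26 genes, 24 were higher in all 3 pairs. In the limma fit over the 6 libraries 17 rose when adjusted over the list alone, with 0 passing over all genes. Here and below, adjustment over a list alone is not corrected across the lists. INSIG1 (chromosome 7, 155297776 to 155310235), a sterol sensor that holds SREBP proteins in the endoplasmic reticulum, rose by 1.73 (SE 0.17, adjusted p = 0.00124 over the list alone, limma with Benjamini-Hochberg adjustment). MSMO1, a sterol methyl oxidase, rose by 1.32 in the same way, and FDFT1, squalene synthase, by 1.15.

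Fatty acid synthesis genes were higher as well, with medians of 0.43, 0.45 and 0.21 over 20 members in untransfected, control siRNA and EHMT2 siRNA cells. SCD (chromosome 10, 100347124 to 100364834), which desaturates stearoyl-CoA, had an FPKM of 650.0 in resistant and 152 in parental untransfected cells, and 756 and 188 with control siRNA. It rose by 1.95 (SE 0.18, adjusted p = 0.00137 over the list alone, limma with Benjamini-Hochberg adjustment). FASN, fatty acid synthase, rose by 1.02 in the same way, ACSL3 by 0.85, SREBF1, the transcription factor of this programme, by 0.67 and FADS1 by 0.56. The other 15 members did not pass. ACSL5, an acyl-CoA synthetase, went the other way, with a ratio of −4.15 in untransfected cells and −0.66 with control siRNA.

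Interferon-stimulated genes were higher in resistant cells too, with medians of 1.36, 0.20 and 0.40 over 36 members and 19 members higher in all 3 pairs. Of 29 tested members, 5 rose when adjusted over the list alone, each with an adjusted p of 0.0233 (limma with Benjamini-Hochberg adjustment). These were IFITM1 (1.08) and BST2 (1.07), membrane proteins that restrict viruses, IRF7 (0.90), IFI35 (0.96), and the OAS1 locus (2.02), which the files list as AC004551.1. The size differed between pairs: IFI6 had an FPKM of 257.5 against 18.1 in untransfected cells, and 10.6 against 8.58 with control siRNA. Messages encoded by mitochondrial DNA were lower in resistant cells, with medians of −0.87, −1.28 and −0.56 over 13 members. Of these, 11 were lower in all 3 pairs, among them MT-CYB with ratios of −1.41, −1.33 and −0.82, and 0 passed the test over the list alone. In the untransfected pair MT-ND6 (0.48) and MT-ND5 (0.30) went against the others.

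Further genes chosen by rule for a like ratio in the untransfected and control siRNA pairs were NRP1, a co-receptor of semaphorins and VEGF (1.49 and 2.37), FOSL1, an AP-1 subunit (1.55 and 1.37), MAL2, which acts in epithelial transcytosis (1.43 and 1.31), KRT15, a keratin (1.30 and 1.55), and DPYSL2, a microtubule-binding protein (1.26 and 1.22). AL139300.1 was higher as well, but all its exonic bases are shared with KLC1 and APOPT1, so its level is uncertain. Lower genes were ID2, an inhibitor of helix-loop-helix factors (−1.21 and −2.14), RGS2, which shortens G protein signals (−2.12 and −1.86), ABCC2, the MRP2 efflux pump (−2.17 and −1.28), HAS3, a hyaluronan synthase (−1.47 and −1.23), PRKACB, a catalytic subunit of protein kinase A (−3.67 and −1.12), NECTIN3, an adhesion molecule (−1.28 and −1.10) and FSD1 (−2.54 and −0.98). MT-ND2, MT-ATP6 and MT-CO3 completed that side, with PCDH7, a protocadherin listed at 0 in untransfected resistant cells and at 33.1 in untransfected parental cells. ABCC2 fell in the 6-library fit when adjusted over the list alone of drug efflux transporters (−1.51, SE 0.25, adjusted p = 0.0114, limma with Benjamini-Hochberg adjustment).

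TYMS, which encodes thymidylate synthase, the target of 5-fluorouracil, separated the pairs. Its FPKM was 294 in resistant and 46.1 in parental untransfected cells, a ratio of 2.65. With control siRNA the values were 61.2 and 92.4, and with EHMT2 siRNA 24.6 and 42.1, so that the ratios were −0.59 and −0.76. TYMS shares 39.1% of its exonic bases with ENOSF1, which makes its exact level uncertain, but its neighbours moved alike. USP14, a proteasome-bound deubiquitinase, and THOC1, an mRNA export factor, had ratios of 2.44 and 2.58 in the untransfected pair, against −0.09 and −0.61 with control siRNA. All 41 measured genes of the short arm of chromosome 18, from 158383 to 14132490, were higher in untransfected resistant cells, 37 of them at least 2-fold. Their median was 1.60 (95% bootstrap interval 1.47 to 1.71). It was 0.14 with control siRNA (0.01 to 0.21) and 0.01 with EHMT2 siRNA (−0.14 to 0.09), where 0 of the 41 reached 2-fold. The 121 genes of the long arm had a median of 0.16 in the untransfected pair. This arm was chosen after its values were seen. A scan of all autosomes in windows of 25 neighbouring genes gave 1.63 as its most extreme median in the untransfected pair, from NDC80 to AFG3L2 on this arm, and −0.52 as the most extreme on any other chromosome. None of 1000 shuffles of the gene order reached 1.63, and the highest gave 0.61.

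**Figure D2:**
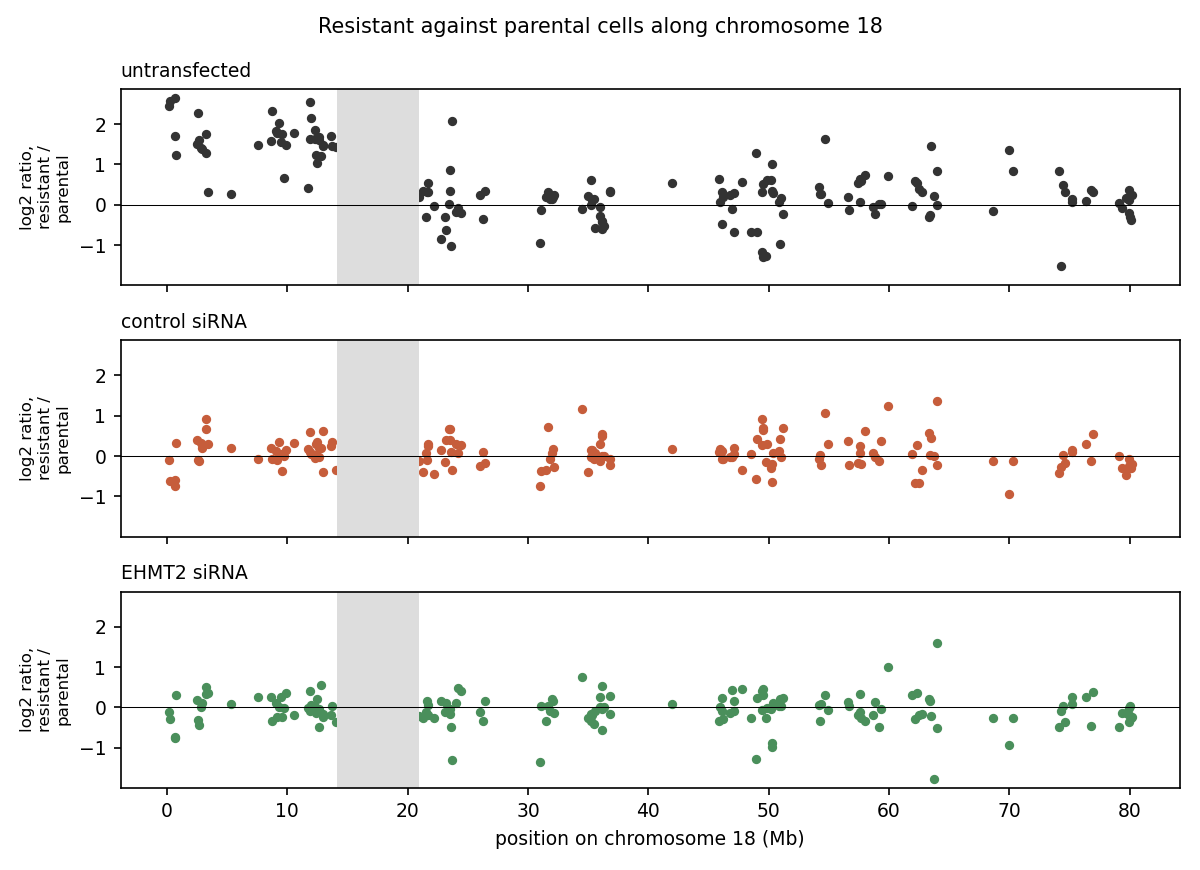
Log2 ratio of resistant against parental cells (vertical axis) for each measured gene along chromosome 18 (horizontal axis, megabases) in the 3 treatments, 1 point per gene, with the gap between the arms shaded in grey. All 41 short arm genes lie above 0 in untransfected cells, with a median of 1.60, and they scatter around 0 in both siRNA pairs.

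Several other groups also had opposite directions without and with siRNA. DNA replication genes had medians of 0.74 in untransfected cells, −0.55 with control siRNA and −0.44 with EHMT2 siRNA. G2/M genes had 0.52, −0.42 and −0.55, and DNA repair genes 0.31, −0.26 and −0.20. ATF4 targets, which answer to amino acid shortage, had −0.57, 0.93 and 0.69, with DDIT3 at −0.65, 2.40 and 1.58. Cytosolic ribosomal proteins had −1.07, 0.57 and 0.35, immediate early genes −0.43, 0.76 and 0.41, and heat shock genes 0.56, −0.52 and −0.19. In the limma fit over the 4 siRNA libraries, 22 of 32 ATF4 targets rose in resistant cells, with 0 falling, while 15 of 40 replication genes and 17 of 39 G2/M genes fell, with 0 rising (adjusted over all genes). In the 6-library fit 0 members of these lists passed for the line, even when adjusted over each list alone. Genes that activate or break down fluoropyrimidines had medians of 0.24, 0.12 and 0.08, inside the range of random lists. Among them were NT5E, a 5′-nucleotidase (1.28 and 0.96 in the untransfected and control siRNA pairs), TYMP, thymidine phosphorylase (0.54 and 0.12), UMPS, which makes the active nucleotide (−0.01 and −0.24), UPP1, uridine phosphorylase (−0.20 and 1.18) and TK1, thymidine kinase (0.28 and −0.55). DPYD, which degrades 5-fluorouracil, was below 1 FPKM in every library. CDKN1A, the p53-induced cell cycle inhibitor, had ratios of 1.01, 0.44 and −0.10.

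At the 2-fold size, 408 genes were higher and 460 lower in untransfected resistant cells, 185 and 111 with control siRNA, and 184 and 185 with EHMT2 siRNA. With values rescaled to the same sum in each library, these counts were 1114 and 520 in untransfected cells and 340 and 633 with EHMT2 siRNA, so the share in each direction depended on the scaling. Across genes, which are not independent replicates, the control and EHMT2 siRNA pairs correlated with r = 0.635, and 256 of 278 genes 2-fold apart in the control siRNA pair (92.1%) kept their sign. The untransfected and control siRNA pairs correlated with r = −0.174, and 325 of 783 genes (41.5%) kept their sign. The 6-library limma fit with Benjamini-Hochberg adjustment called 0 of 11521 genes for the line, with 603 at an unadjusted p under 0.05 and a lowest adjusted p of 0.318. Restricted to the 4 siRNA libraries, the same model called 1032 genes, 517 higher and 515 lower in resistant cells. All p-values here measure only the spread among these libraries, with the interaction of line and treatment as the error.

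The next comparison asked what loss of EHMT2 does in each line, and here the lines moved together. Genes of cell division were lower with EHMT2 siRNA in both. Replication genes had medians of −0.72 in resistant and −0.77 in parental cells, with 37 of 40 lower in both lines, and G2/M genes had −0.74 and −0.71, with 36 of 39 lower in both. In the fit over the 4 siRNA libraries 33 replication genes and 32 G2/M genes fell, and 0 rose (limma, adjusted over all genes). In the 6-library fit 4 and 3 of them fell when adjusted over the list alone. MCM5, a subunit of the replicative helicase, fell by 2.07, MCM3 by 1.53, AURKB, a mitotic kinase, by 1.54 and PRC1, which bundles spindle microtubules, by 1.40. Genes of thymidylate and folate metabolism had medians of −0.36 and −0.43. RRM2, the ribonucleotide reductase subunit, had ratios of −1.48 and −1.08, and TYMS −1.29 and −1.12. In the list of fluoropyrimidine activation and breakdown, TK1 fell by 2.09 (SE 0.30, adjusted p = 0.00302 over that list alone, limma with Benjamini-Hochberg adjustment), and SLC29A1, a nucleoside transporter, fell by 1.39 in the same way, whereas NT5E rose by 1.70. DNA repair genes had medians of −0.25 and −0.40, and serine and glycine synthesis genes −0.55 and −0.56, with SHMT1 falling by 1.08.

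Ribosomal protein messages were lower too, with medians of −0.67 in resistant and −0.54 in parental cells and 69 of 77 members lower in both. In the 4-library limma fit 55 of the 77 fell and 0 rose, while 0 passed in the 6-library fit, over the list alone or over all genes. RPS3 had ratios of −1.78 and −1.46, and RPL14 of −1.46 and −1.46.

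The measured replication-dependent histone genes were higher with EHMT2 siRNA, with medians of 1.07 in resistant and 1.41 in parental cells. Of 52 listed genes only 18 were measured, 17 of them higher in both lines, so the medians cover a part of this family. How fully the library preparation captured histone messages was not examined. The rise therefore holds for the captured messages and is not shown for the total output of these genes. Some levels were low, as HIST1H2BC had an FPKM of 0.207 in resistant and 0.762 in parental cells with control siRNA. All 9 tested members rose in the 6-library fit when adjusted over the list alone and in the 4-library fit over all genes, among them the core histone genes HIST1H2BC (2.40) and HIST1H2BD (2.15) and the linker histone gene HIST1H1C (1.90). HIST2H2AA3 and HIST2H2AA4, near-identical copies whose reads may be divided between them, had ratios of 2.37 to 2.74. HIPPO-YAP targets had medians of 0.76 and 0.94, and 9 of 20 rose in the 6-library fit when adjusted over the list alone, among them AJUBA, a LIM protein that binds LATS kinases (1.98), TEAD4, the DNA-binding partner of YAP (1.17) and again NT5E. Interferon-stimulated genes had medians of 0.71 and 0.50, with 28 of 36 higher in both lines, and 19 of 29 rising and 1 falling in the 4-library fit, against 2 rising in the 6-library fit when adjusted over the list alone. With control siRNA against untransfected cells this list had medians of −1.38 in resistant and −0.12 in parental cells. The 0.71 in resistant cells thus does not show a level above that of untransfected cells. IRF7 rose by 1.54, and IRF9, the DNA-binding part of the interferon response complex, had ratios of 2.03 and 1.70.

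Hypoxia and glycolysis genes had medians of 0.65 and 0.40, but the members split, with 5 rising and 3 falling of 35 in the 6-library fit when adjusted over the list alone. SLC2A3, a glucose transporter, rose by 2.47, ANGPTL4, a lipase inhibitor, by 1.90 and P4HA1, a collagen prolyl hydroxylase, by 1.48, whereas the glycolytic enzymes GAPDH, TPI1 and PFKL fell by 1.54, 0.91 and 0.82. NRF2 targets had medians of 0.38 and 0.44, with 3 of 26 rising in the same way, among them OSGIN1 by 2.59 and SRXN1, sulfiredoxin, by 1.63. Autophagy and lysosome genes had medians of 0.40 and 0.43, with 8 members rising, including MAP1LC3B (1.72), OPTN (1.30) and SQSTM1 (0.79), and 4 falling, including CTSD, cathepsin D (−1.11). The p53 targets had medians of 0.34 and 0.50, and 16 of 29 rose in the 4-library fit, while 0 passed in the 6-library fit, over the list alone or over all genes. PHLDA3 had ratios of 2.30 and 0.87. CDKN1A had −0.21 and 0.33. Germline genes, which H3K9 methylation helps to silence in many cells, had medians of 0.43 and 0.70, with 7 of the 43 listed genes measured. The medians lay inside the range of random lists, at percentiles of 88.9 and 97.3. Of the 7 members, 6 were higher in both lines and 0 lower in both. In the 4-library fit 4 of 5 tested members rose and 0 fell, while 0 passed in the 6-library fit over the list alone.

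**Figure D3:**
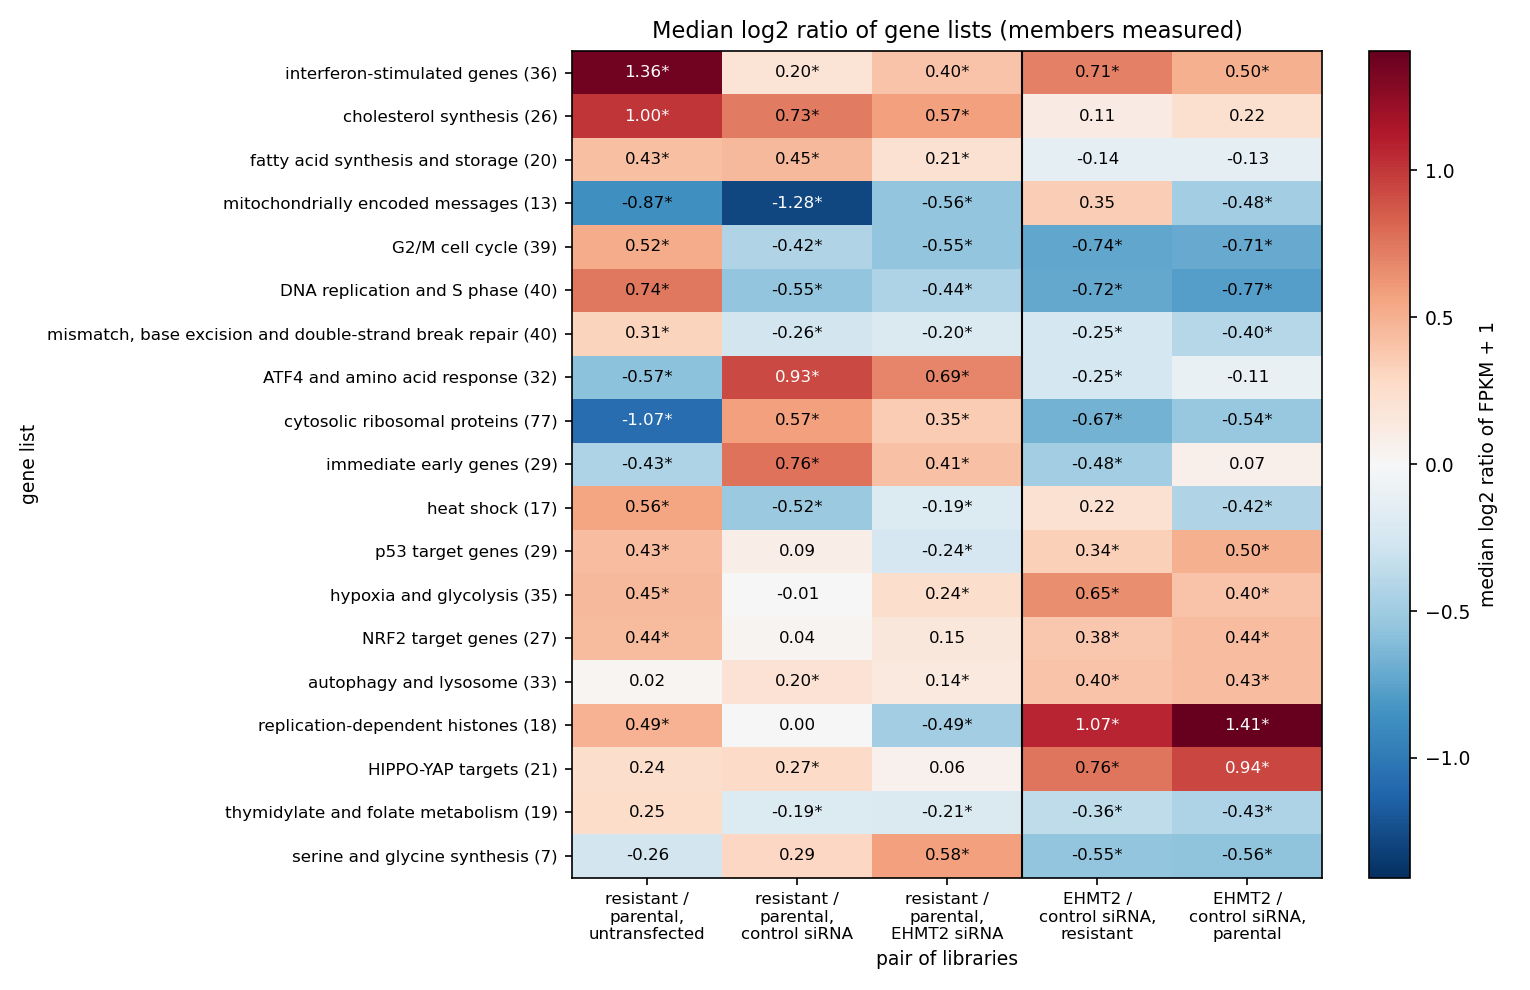
Median log2 ratio of gene lists (vertical axis, number of measured members in brackets) in 5 pairs of libraries (horizontal axis), with red for higher and blue for lower and a star for medians outside the 2.5 to 97.5 percentile range of random lists. Cholesterol synthesis was higher in all 3 line pairs, and replication genes had opposite signs in the untransfected pair (0.74) and the control siRNA pair (−0.55).

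The single genes with the largest ratios in both lines, chosen by rule, were TNNC1, a troponin subunit (2.87 in resistant and 2.69 in parental cells), BEST1, a chloride channel (3.59 and 2.79), CCDC84 (2.13 and 2.72) and S100A10, the annexin A2 partner (2.28 and 2.06). BEST1 had an FPKM of 14.9 in untransfected parental cells, 0.767 with control siRNA and 11.2 with EHMT2 siRNA, so its parental ratio comes from a low control siRNA library and not from a level above that of untransfected cells. ACAP1 was listed at 0 in resistant cells with control siRNA and had a ratio of 2.67 in parental cells. On the lower side stood CFL1, the actin-severing protein cofilin, whose FPKM was 544 with control siRNA and 99.4 with EHMT2 siRNA in resistant cells, and 548 and 127 in parental cells. With it were CHPF, which polymerises chondroitin (−2.12 and −2.16), SERPINH1, a collagen chaperone (−2.01 and −2.31), ADAM19, a metalloprotease (−1.97 and −2.42), NME4, a mitochondrial nucleotide kinase (−2.23 and −2.43), PDE4B, a cAMP phosphodiesterase (−2.02 and −2.04) and NRGN, which binds calmodulin (−2.16 and −1.99). In resistant cells NME4 and PDE4B had an FPKM of 1.59 and 0.577 without siRNA, 45.8 and 24.8 with control siRNA and 8.98 and 5.38 with EHMT2 siRNA, so they were not below the untransfected level there. PIK3R2 and BLOC1S5-TXNDC5 were lower as well, but share 87.2% and 100% of their exonic bases with other genes, so their levels are uncertain.

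At the 2-fold size 613 genes were higher and 475 lower with EHMT2 siRNA in resistant cells, and 894 and 419 in parental cells. The ratios correlated across genes between the lines (r = 0.826), and 1028 of 1046 genes (98.3%) kept their sign. Both lines shared 399 genes at least 2-fold higher, where independent lists would share 40.7, and 271 lower, where they would share 16.4. The 4-library limma fit with Benjamini-Hochberg adjustment called 4902 genes, of which 2746 rose and 2156 fell. The fit over all 6 libraries called 0, with 3060 genes at an unadjusted p under 0.05 and a lowest adjusted p of 0.0529.

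**Figure D4:**
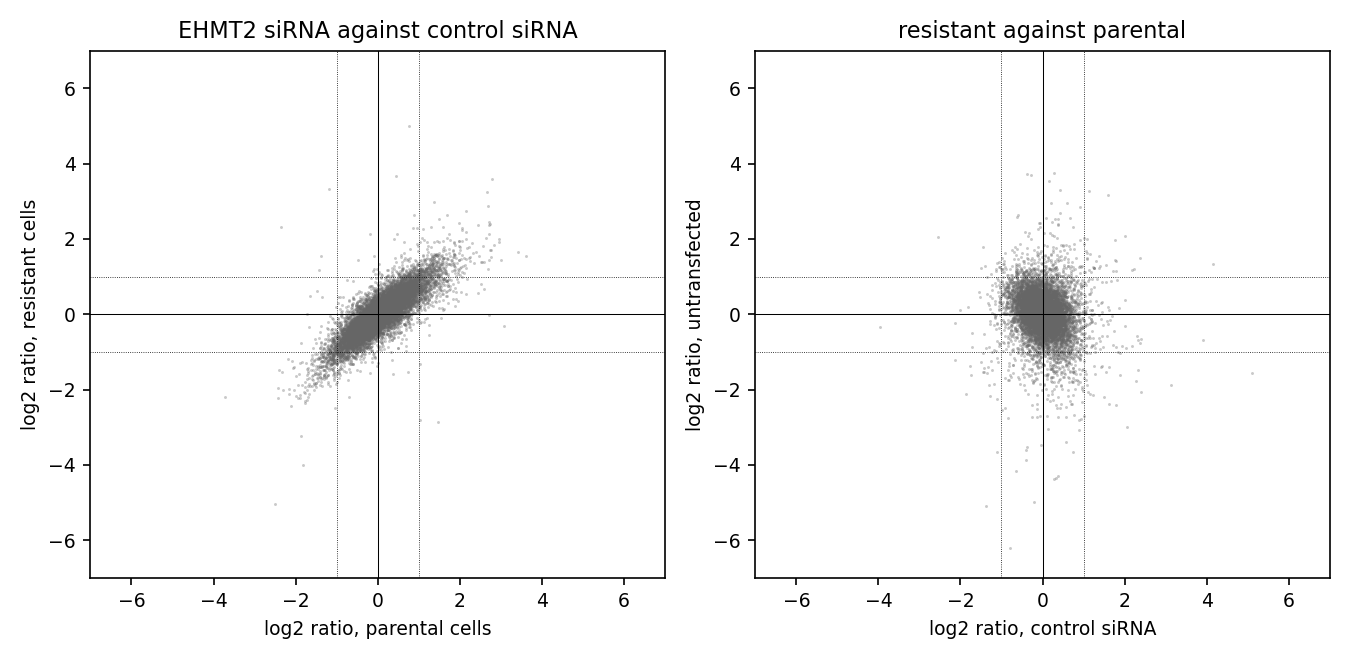
Log2 ratios of single genes, 1 point per gene. The left panel sets EHMT2 siRNA against control siRNA in parental (horizontal) and resistant cells (vertical), where r was 0.826, and the right panel sets resistant against parental cells with control siRNA (horizontal) and untransfected (vertical), where r was −0.174. Dotted lines mark 2-fold.

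Whether EHMT2 siRNA moved resistance-associated genes back towards parental levels was read in genes 2-fold apart between the untransfected lines, a pair that shares no library with the siRNA pairs. With EHMT2 siRNA against control siRNA, the 408 genes higher in resistant cells had medians of 0.21 in resistant and 0.33 in parental cells, both at percentile 100 of matched random lists. The 460 lower genes had medians of −0.27 and −0.31, both at percentile 0. These ratios start from the control siRNA level, which in resistant cells was often far from the untransfected level that defined the genes. IFI6, for example, had an FPKM of 258 in untransfected resistant cells, 10.6 with control siRNA and 43.4 with EHMT2 siRNA, so the medians do not show levels beyond those of untransfected resistant cells. In resistant cells 155 of the 408 (38.0%) and 156 of the 460 (33.9%) had ratios against the direction of the untransfected pair. Among the genes of cholesterol and fatty acid synthesis, SCD fell by 1.18 with EHMT2 siRNA, with SREBF2, a transcription factor of the cholesterol pathway, falling by 1.16 (6-library fit, adjusted over the list alone), while IDI1, isopentenyl diphosphate isomerase, rose by 0.99. INSIG1 had ratios of −0.31 and 0.02. For the 185 genes higher and 111 lower in the control siRNA pair the medians in resistant cells were −0.18 and 0.14, opposite to the direction of that line pair. The −0.18 lay at percentile 0 of matched random lists, but the 0.14 at 87.9, inside their range. In parental cells the medians were 0.28 and −0.36. The control siRNA line pair shares a library with each knockdown pair. In a simulation without effects and with equal noise in each library, such sharing gave correlations of −0.50 with the resistant and 0.49 with the parental knockdown ratios. The observed values were −0.122 (covariance −0.03) and 0.137 (covariance 0.03). The real knockdown ratios hold a part shared by both lines (r = 0.826), which the simulation lacks, so the simulated and observed values cannot be compared in size.

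Some genes differed in their response to EHMT2 siRNA between the lines, without a test of the difference. ITM2B, a transmembrane protein that is cleaved by furin, had ratios of 2.63 in resistant and 0.89 in parental cells, and CPA4, a carboxypeptidase, 1.20 and 2.69. In resistant cells ITM2B had an FPKM of 54.3 without siRNA, 12.6 with control siRNA and 83.4 with EHMT2 siRNA. CPA4 had 5.11, 22.7 and 53.4 in the same order. Both differences thus depend on the control siRNA library of resistant cells, which lay far from the untransfected level. FOS, the AP-1 subunit, had 0.61 and −1.49, SOD2, the mitochondrial superoxide dismutase, 0.92 and −0.75, and TMEM33 −0.84 and 0.69. PDXP, IFI30, PIK3R2, AC023055.1, AL157935.2 and AC004922.1 differed as well, but share exonic bases with other genes, so their levels are uncertain.

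As a background, control siRNA was compared with untransfected cells of each line. The immediate early genes FOS and FOSB were far lower with control siRNA in both lines. FOS had an FPKM of 4.93 against 237 in resistant cells and ratios of −5.33 in resistant and −4.43 in parental cells, and FOSB, chosen because the test called it, fell by 5.07 (SE 0.24, adjusted p = 0.0113, limma with Benjamini-Hochberg adjustment). The globin genes HBB, HBA1 and HBA2, called by the same test, rose by 4.89, 3.94 and 4.05. SENP3-EIF4A1, the fifth gene called, shares 88.0% of its exonic bases with EIF4A1 and SENP3 and is uncertain. Epithelial genes were lower in both lines, with medians of −0.51 in resistant and −0.36 in parental cells. In resistant cells interferon-stimulated genes had a median of −1.38 and ribosomal proteins of 1.09, against −0.12 and −0.56 in parental cells. At the 2-fold size 503 genes were higher and 451 lower in resistant cells, and 111 and 242 in parental cells. Rescaled to the same sum, the counts were 725 and 873 in resistant and 444 and 289 in parental cells. The more frequent direction thus turned in both lines, and in resistant cells it also turned at 1.5-fold (1296 and 1542) and with a pseudocount of 0.1 (724 and 770).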

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

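The tests of label exchange, of the library that stands apart, of file order, of the short arm of chromosome 18, of globin and of other splits were chosen only after the results were seen, whereas both tests of ribosomal proteins were written before theirs.

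Several groups of genes had opposite directions between the lines without and with siRNA, a difference that was not tested. In the untransfected pair the medians were 0.52 for G2/M genes, 0.74 for replication genes, 0.31 for DNA repair genes, −0.57 for ATF4 targets, −1.07 for ribosomal proteins, −0.43 for immediate early genes and 0.56 for heat shock genes, and every one had the other sign in both siRNA pairs.

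An exchange of the untransfected labels is argued against as the whole cause by 4 of 13 lists that kept the direction of both siRNA pairs in the untransfected pair, cholesterol synthesis among them. Other values go with an exchange but restate the pattern that raised the question, so they add no support. Of the 13 lists 7 turned. Exchanging the untransfected libraries in the limma fit gave 2458 genes at an unadjusted p under 0.05, against 603 with the labels as given. The same resistant cells with and without siRNA are argued against by the short arm of chromosome 18, whose median line ratio was 1.60 without siRNA and at most 0.14 in the siRNA pairs. Untransfected resistant cells stood apart, with a highest correlation of 0.943 with the other libraries without EHMT2 siRNA, where those correlated at 0.962 or more. Libraries did not lie nearest to their own line. Resistant cells with control siRNA correlated at 0.935 with untransfected resistant cells, but at 0.968 with untransfected parental cells and 0.970 with parental control siRNA cells. Untransfected parental cells correlated at 0.962 with parental control siRNA cells, below that 0.968. A candidate explanation is a resistant subline or passage with a gain of that arm, which DNA was not at hand to test. A processing batch that shifts both untransfected libraries alike would leave their line ratios unchanged, so it is argued against. The short arm of chromosome 18 moved with control siRNA in resistant cells (−1.55) and not in parental cells (0.06). A batch that acts unlike on the untransfected libraries, whose rows stand in another order, cannot be told apart from transfection. As list members, the genes of that arm are argued against, since the 7 lists stayed opposite without them. Only the G2/M list held such a gene, and its medians without it were 0.50, −0.43 and −0.56. An effect of that arm on genes elsewhere was not tested.

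Ribosomal protein messages were lower with EHMT2 siRNA in both lines. A trend with gene length is argued against, because the list lay below its nearest other genes in length and expression by −0.87 in resistant and −0.53 in parental cells (95% bootstrap intervals −0.95 to −0.79 and −0.64 to −0.43). The scaling of the values is argued against as well, since the median stayed at −0.41 or lower under 3 other scalings. A lower output of ribosomal protein messages after loss of EHMT2 is one hypothesis, and an effect of this siRNA on other targets was not tested and stays open. In resistant cells the list had a median of 1.09 with control siRNA against untransfected cells, and −0.56 in parental cells. The fall in resistant cells can therefore also reflect a high control siRNA library.

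The globin genes HBA1, HBA2 and HBB summed to between 63.2 and 81.1 FPKM in the siRNA libraries and to at most 1.96 in the untransfected ones. RNA of blood cells cannot be told apart from other sources, because only 1 of the 10 other erythroid markers listed at 0 in both untransfected libraries was seen, at 0.287 FPKM in 1 siRNA library, and the depth that would show them at this globin level is unknown. HBG1 and HBG2 were listed in the untransfected libraries too and decide nothing. A source shared by the 4 siRNA libraries, such as a run or reagent, could give sums that differ by only 1.28-fold between them, but transfection itself is confounded with it.

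With EHMT2 siRNA, single genes had ratios of opposite sign in the lines, again without a test of the difference. FOS had 0.61 in resistant and −1.49 in parental cells, SOD2 0.92 and −0.75, and TMEM33 −0.84 and 0.69. PDXP had 2.12 and −0.18, but the parental value is close to 0, the resistant value rests on 1 low library (FPKM 2.73 with control siRNA, against 12.2 to 15.2 in the others), and 62.6% of its exonic bases are shared with another gene.

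The 6 libraries can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. The real split by line called 0 genes in limma and the highest other split called 18, and with 0 real calls the number of splits with as many is fixed and decides nothing. At an unadjusted p under 0.05 the real split gave 603 genes, and the split that exchanges the untransfected libraries gave 2458. The higher count follows from the opposite line ratios without and with siRNA, so it restates that pattern and adds no support.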

How the results depend on the processing

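The counts without genes that share exonic bases and the alternatives for the short arm of chromosome 18 were chosen after seeing the data, and all other alternatives before. No paired analysis was possible by replicate number because each group holds only replicate 1, while the additive fit already compares the lines within treatments and the treatments within lines.

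EHMT2 was at least 2-fold lower in both knockdown pairs under all alternatives run. Of 555 alternative list values 536 kept their side of the percentile bounds, 12 moved outside, 7 moved inside and 0 reversed, and of 288 for named genes 283 kept their side of the 2-fold size, 4 passed it and 1 lost it. The short arm of chromosome 18 had a median of 1.53 to 1.68 in the untransfected pair.

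Counts of genes 2-fold apart depended on the pseudocount, the scaling and by construction on the size asked for. With a pseudocount of 0.1 they were 1351 between untransfected lines (main value 868), 574 with control siRNA (296), 836 with EHMT2 siRNA (369), 1738 for knockdown in resistant (1088) and 2061 in parental cells (1313), and 1494 (954) and 709 (353) for control siRNA in resistant and parental cells. With values rescaled to the same sum they were 1634, 596, 973, 1803, 2397, 1598 and 733 in the same order. At 1.5-fold they were 2562, 1388, 1849, 3479, 3938, 2838 and 1763, and at 4-fold 113, 28, 23, 62, 82, 119 and 34. With an FPKM of 5 the EHMT2 siRNA line pair gave 238. Rescaling raised values above 0 relative to the pseudocount and shifted each pair by the ratio of its library sums, which moved the median of all genes from 0.07 to 0.31 in the untransfected pair, from 0.05 to 0.11 and from 0.07 to 0.19 in the resistant and parental knockdown pairs, and from 0.05 to 0.22 for control siRNA in parental cells. The share of higher genes then was 68.2% (47.0% before) between untransfected lines, 34.9% (49.9%) with EHMT2 siRNA, 66.7% (56.3%) and 78.8% (68.1%) for knockdown in resistant and parental cells, 45.4% (52.7%) and 60.6% (31.4%) for control siRNA in resistant and parental cells, and 37.8% in the EHMT2 siRNA line pair with a pseudocount of 0.1. The more frequent direction also turned in the untransfected pair at 1.5-fold (1388 higher and 1174 lower) and with an FPKM of 5 (317 and 295). It turned for control siRNA in resistant cells at 1.5-fold (1296 and 1542) and with a pseudocount of 0.1 (724 and 770), and for knockdown in resistant cells after median-centring (534 and 541, against 613 and 475). In the EHMT2 siRNA line pair, nearly even at first, it turned with an FPKM of 5, after median-centring, at 4-fold and without genes that share exonic bases.

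The limma calls depended on the untransfected libraries. The 4 siRNA libraries alone gave 1032 calls for line and 4902 for EHMT2 siRNA, against 0 and 0 with all 6. Leaving out 1 library at a time, where the lone library of a group is assumed to vary like the others, gave 0 to 1034 for line, 0 to 4904 for EHMT2 siRNA and 3 to 2059 for control siRNA (5 with all). Without the untransfected resistant library the counts were 1018, 4903 and 413, and without the untransfected parental library 1034, 4904 and 2059, since either leaves the untransfected level of 1 line only. Without parental EHMT2 siRNA the knockdown count was 1, and control siRNA counts were 3 without either control siRNA library and 11 without either EHMT2 siRNA library. Asking for an FPKM of 5 gave 263 knockdown calls, and a pseudocount of 0.1 gave 3 for control siRNA.

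Genes taken from the control siRNA pair instead of the untransfected pair reversed the sign for resistance genes in resistant cells (−0.18 for the higher and 0.14 for the lower genes). Only the higher genes lay outside the range of random lists, as the 0.14 was at percentile 87.9. The control siRNA pair shares a library with the knockdown. With an FPKM of 5 the share of genes keeping their sign was 35.4% (41.5%) for untransfected against control siRNA line ratios, 97.4% (92.1%) for control against EHMT2 siRNA, and 99.8% (98.3%) between knockdowns. For all other changes the cause was not tested. Depth is unknown, so no limit can be set for genes listed at 0, which weigh most with a pseudocount of 0.1.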

Other observations

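The genes here were chosen after their values were seen. A few genes were listed at 0 in every resistant library and above 1 FPKM in every parental library. HNF4A, a transcription factor of intestinal epithelium, had an FPKM of 1.68, 1.69 and 1.95 in parental cells that were untransfected, given control siRNA and given EHMT2 siRNA. ICAM1, an adhesion molecule for leukocytes, had 2.70, 1.48 and 2.57. Of 9 genes listed at 0 in both siRNA libraries of one line and at 1 FPKM or more in both of the other, 5 went the same way in the untransfected pair, 2 the opposite way and 2 were at 0 in both. ICAM1 fell in resistant cells in the 6-library fit when adjusted over the list alone of NF-kB and cytokine genes (−1.68, SE 0.21, adjusted p = 0.00467, limma with Benjamini-Hochberg adjustment), in which LCN2 (0.99), TNFAIP3 (0.86) and BIRC3 (0.72) rose.

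Further genes moved with EHMT2 siRNA in the 6-library limma fit when adjusted over their list alone. CXCL8, a neutrophil chemokine, rose by 1.35 and ACTA2, smooth muscle actin, by 1.30, while KRT19, an epithelial keratin, fell by 1.67, CDH3, P-cadherin, by 1.22 and PLAU, urokinase, by 1.21. Markers of other cell types were few: 2 leukocyte, 4 fibroblast and 3 endothelial markers reached 1 FPKM in any library. Lists outside the range of random lists in no line or knockdown pair were H3K9 demethylases, Polycomb, germline genes, anti-apoptotic and pro-apoptotic genes, Wnt targets and endoplasmic reticulum chaperones.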
